A study of Bacillus subtilis with 9 samples.

How the data were processed

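Genomic DNA of Bacillus subtilis PY79, a laboratory strain, was sequenced in 9 libraries, numbered 1 to 9 as in their titles. Per the labels, every culture was started at an optical density of 0.05, grown with shaking at 30 °C and harvested at an optical density between 0.65 and 0.9; the density of each single culture is not given in the sources used here. The series text names a ccrZ mutant, a yabA::cat mutant and the double mutant, whereas the growth text of every library speaks of wild-type cells. No label ties a library to a strain or to a replicate, so all 9 libraries were left without a group. No comparison between genotypes was made, no mean or SD over libraries is given as a result, and no library was given a genotype from its values. Sums or means over libraries were used as steps of the computation, such as placing the terminus, filtering and sorting bins, simulating counts and forming the reference of the mirror correlation.

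The authors deposited read counts, not scaled by depth, for 4034 consecutive bins of a chromosome named PY79 with a length of 4033459 bp, per the file headers and the bin coordinates. Bins were 1 kb long except the last, which was 459 bp. The submitters' processing notes name BWA, SAMtools and bedtools. Their versions and the treatment of duplicate reads are not given in the sources used here. No mapping quality minimum is stated, though the name of the deposited counts carries the tag q20, whose meaning is not explained. A second deposited table held the same values and was not used. A gene table of strain 168 (ASM904v1) was at hand, which is another build, so only its gene names and gene order were used. No annotation of the PY79 sequence was used here. For this reason yabA, ccrZ, rtp, the other loci of the fixed list and the mobile elements were not placed and are not analysed here, and regions are given by their 1-based positions in the deposited bins.

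Choices in this and the next paragraph were made before the data were examined, except where said. The short last bin was left out, once its length had been seen, and so were 38 bins at 0 in every library, which left 3995 bins. The origin was taken at coordinate 1, where sequences of this chromosome start, next to dnaA. The terminus was the lowest point of a running mean over 200 kb of the profile summed over libraries that had each been scaled to the same total. The origin-to-terminus ratio was the mean count of bins within 100 kb either side of the origin over that of bins within 100 kb either side of the terminus. The slope of each arm was a least squares line of log2(count + 1) on distance from the origin. Intervals at 95% came from a block bootstrap of 1000 draws with blocks of 20 adjacent bins. They measure the unevenness of coverage along the chromosome within a library and not the spread between cultures.

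The local ratio of a bin was its count plus 1 over the median of 20 bins on each side plus 1. The rule for named places took every run of adjacent bins at 0 in all libraries if there were 10 or fewer, and the 10 bins with the widest range of the log2 local ratio across libraries among bins with a mean count of at least 20, adjacent bins counted as 1. The range was set beside Poisson simulations, as planned; their number, 200, and the limit, which the most extreme of all bins passed in 5% of simulations, were set after the data were seen. Pairs of libraries were compared by chi-square over its degrees of freedom. A pair was called within the sampling noise where the upper tail p was at least 0.05, a threshold also set later. A correlation of the ratio with the total count was planned only if the ratios did not fall into separate clusters. The correlation was not computed, because 4 pairs of neighbouring values had intervals apart. This criterion was chosen after the values were seen and leaves out the spread between cultures, so whether the ratio is related to depth was left untested. Poisson intervals of counts were exact. All such intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

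Further measures were chosen after the data had been looked at, from profiles, pairwise scatter and coverage steps of all libraries. These were the bands at 0 to 100 kb and 300 to 450 kb from the origin, for which bins under 0.75 times their flanks were left out and 3964 remained; the scatter of read splits around a running mean of 101 bins; the mirror correlation, computed for all 9 libraries in bins of 25 kb to 1000 kb from each of 161 axes; the steps across 7 clusters of empty bins; and the spacing of empty runs against rRNA operons.

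The methods were tested on simulated counts on 3995 bins. For the ratio, 4 simulated libraries came out within 0.936% of the true value, and 8 slopes within 0.652%. These were Poisson counts around straight arms with a shared terminus, without the uneven coverage of real libraries. The errors on the real libraries can therefore be larger. The terminus was placed 27 kb from its true position. Of 20 bins set to 0.5 times in 1 library, 20 were among the 20 most variable. The scatter of read splits had a mean of 0.999 over 100 draws of Poisson counts, with single draws from 0.949 to 1.05, and of 0.865 where each start position was taken once, against 0.863 by construction. The alternatives tried were other windows, medians, fitted lines, the terminus at the midpoint of the chromosome length, other filters on bins, other fits and pseudocounts, other flanks and block lengths, and, added after the data were seen, counts corrected for taken start positions and an origin window at the highest point of the summed profile. Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and Matplotlib 3.10.9.

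Total counts ran from 904439 to 1248741 per library, and the median count per bin from 194 to 298.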

Results

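Marker frequency along the chromosome was measured by sequencing genomic DNA from growing cultures of Bacillus subtilis PY79. In a growing population, sequences near the origin of replication are present in more copies than those near the terminus, and the gradient between them follows how often replication starts and how long a round takes. The series concerns ccrZ, a cell cycle regulator gene, and yabA, whose product restrains initiation through DnaA and the DnaN clamp, with yabA replaced or interrupted by cat, a chloramphenicol resistance gene. Which strain each library came from is not stated in the labels used here, so the effect of either mutation was not compared, and each of the 9 libraries is described by its own values. Total counts in libraries 1 to 9 were 1211455, 1248741, 1160923, 1237568, 1130565, 904439, 930768, 1200265 and 1022608.

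Read counts fell from the region around coordinate 1 to a single low region on the far side of the chromosome in all 9 libraries. In library 3 the fall did not begin at coordinate 1. On its left arm the median count rose from 1.49 times the library's median at 0 to 50 kb to 1.57 times at 200 to 250 kb. In the summed profile the lowest point lay in the bin at 2030001 to 2031000 and the highest in the bin at 4022001 to 4023000. The lowest point stayed in that bin when any 1 library was left out. Single libraries had their own lowest bins at starts from 1943001 to 2031001. The own highest point lay at 4022001 in all libraries except library 1, where it lay at 44001, and library 3, where it lay at 3837001. With the terminus at the pooled lowest point the right arm was 2030.5 kb long and the left arm 2003 kb.

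**Figure D1:**
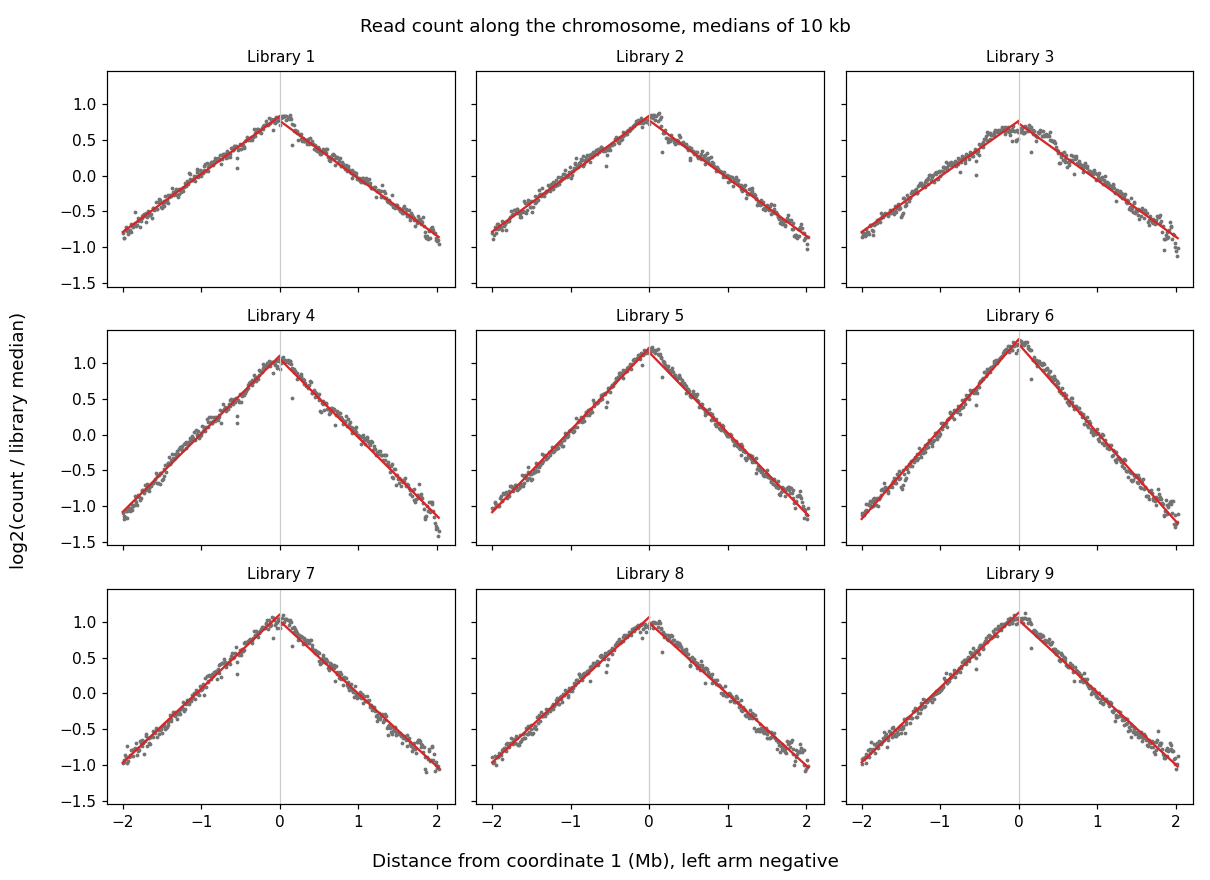
Read count along the chromosome in each library, as log2 of the median count of 10 kb over the library's median (vertical axis) against the distance from coordinate 1 in Mb (horizontal axis, left arm negative). Grey points are medians and red lines are the least squares fits to each arm, with slopes from -0.77 to -1.25 log2 units per Mb.

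The region within 100 kb of the origin held between 2.69 and 4.98 times as many reads per bin as the region within 100 kb of the terminus, with a median of 3.71 over the 9 libraries. The ratio was 2.96 in library 1 (95% interval 2.86 to 3.07), 2.97 in library 2 (2.85 to 3.09) and 2.69 in library 3 (2.57 to 2.83). It was 4.34 in library 4 (4.13 to 4.58), 4.42 in library 5 (4.25 to 4.59) and 4.98 in library 6 (4.78 to 5.20). It was 3.71 in library 7 (3.57 to 3.83), 3.57 in library 8 (3.44 to 3.72) and 3.72 in library 9 (3.61 to 3.85). The highest ratio was 1.85 times the lowest, and their intervals were far apart. Behind each ratio were 185 bins in the origin window and 201 in the terminus window, with 18329 reads in the terminus window of library 6, the fewest, and 34018 in that of library 2, the most. The intervals leave out the spread between cultures, which was not measured for any strain.

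**Figure D2:**
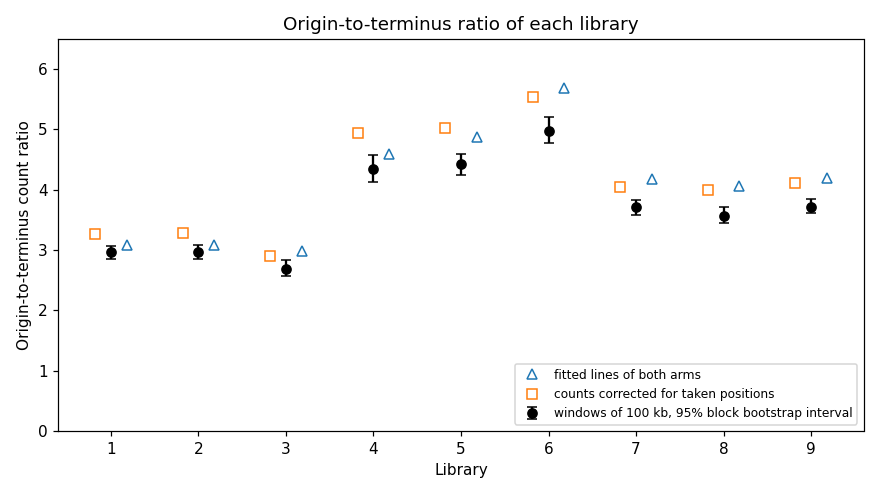
Origin-to-terminus count ratio (vertical axis) of each library (horizontal axis). Black points with bars are the window ratios with their 95% block bootstrap intervals, from 2.69 in library 3 to 4.98 in library 6; triangles are ratios from the fitted lines and squares ratios after correction for taken start positions, without intervals.

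The left and the right arm lost reads at rates whose difference was within its error in each library. On the right arm log2 count changed by -0.80, -0.80, -0.79, -1.09, -1.12, -1.23, -1.01, -0.99 and -1.01 per Mb in libraries 1 to 9, and on the left arm by -0.81, -0.81, -0.77, -1.09, -1.14, -1.25, -1.03, -1.01 and -1.04. The left slope minus the right slope lay between -0.04 in library 9 and 0.02 in library 3. Its 95% interval included 0 in 9 of 9 libraries. The sign of the difference depended on the fit, with the left arm steeper in 7 of 9 libraries by least squares and in 1 of 9 by the Theil-Sen slope. The interval of library 9, from -0.07 to 0.01, reached farthest below 0.

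Counts within 100 kb of coordinate 1 were 1.20 to 1.29 times those at 300 to 450 kb in 8 libraries and 1.05 times in library 3. The bands used here were chosen after the profiles were seen. The median count within 100 kb of coordinate 1, set over that at 300 to 450 kb, was 0.30, 0.28, 0.07, 0.33, 0.36, 0.36, 0.28, 0.26 and 0.28 on the log2 scale in libraries 1 to 9. In library 3 the 95% interval was 0.04 to 0.09, and the value was 0.08 on the right arm and 0.06 on the left. The lowest of the other 8 values was that of library 8, with an interval of 0.23 to 0.29.

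**Figure D3:**
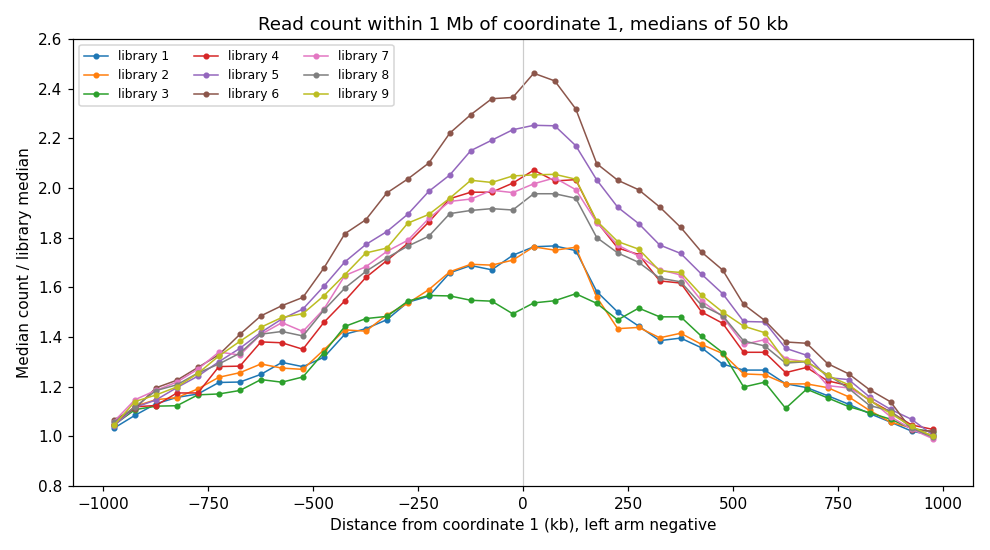
Median count of 50 kb over the library's median (vertical axis) against distance from coordinate 1 in kb (horizontal axis, left arm negative), with 1 line per library. In library 3 the median count within 100 kb of coordinate 1 was 0.07 log2 units above that at 300 to 450 kb, against 0.26 to 0.36 in the other 8 libraries.

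Empty regions were shared by all libraries. There were 10 runs of adjacent bins without a read in any library, 38 bins in all. Of these runs 9 were 4 kb long, at 10001 to 14000, 31001 to 35000, 91001 to 95000, 97001 to 101000, 161001 to 165000, 167001 to 171000, 172001 to 176000, 599001 to 603000 and 910001 to 914000. The other, at 2992001 to 2994000, was 2 kb long and was the only run on the left arm. Within 180 kb to the right of coordinate 1 lay 7 of the 10.

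In the local ratio, 2 bins passed the limit set for counting noise, out of 3993 with a mean count of at least 20. Differences between libraries that are wider than the flanks do not show in this measure. The first of the 2 bins was 2878001 to 2879000. Its log2 local ratio was -0.98, -0.57, -1.0, 0.07, 0.06, 0.20, -0.77, -0.71 and -1.03 in libraries 1 to 9, a range of 1.23 where counting alone gave 0.34 on average, and a deviation of 9.72 SD against a limit of 5.40. In library 9 this bin held 104 reads (exact 95% Poisson interval 85 to 126) and its flanks a median of 214. In library 6 it held 205 reads (178 to 235) against 178.5. The adjoining bin, 2879001 to 2880000, had log2 local ratios of -0.56, -0.52, -0.51, -0.11, 0.07, 0.07, -0.69, -0.71 and -0.55, and did not pass the limit. The second bin was 42001 to 43000. Its log2 local ratio was 0.06, -0.02, 0.05, -0.72, -0.64, -0.58, -0.65, -0.65 and -0.76, a range of 0.83 where counting alone gave 0.23, and a deviation of 8.74 SD. Here library 9 held 274 reads (243 to 308) against a median of 466 in its flanks, and library 1 held 540 reads (495 to 588) against 516.5. Neither place was assigned to a gene, since no annotation of this sequence was used.

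**Figure D4:**
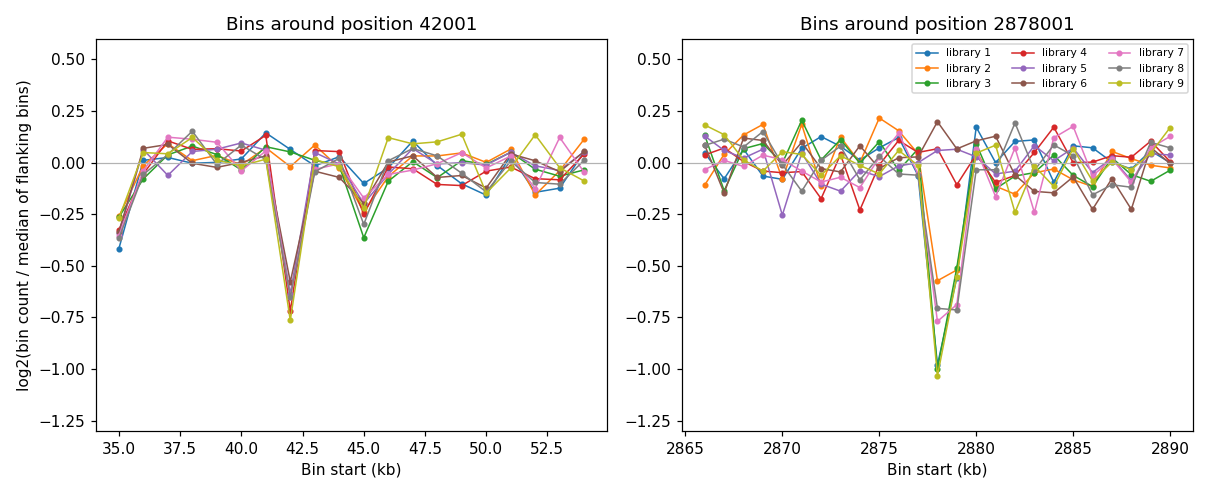
Log2 of the count of each 1 kb bin over the median of its flanking bins (vertical axis) against the start of the bin in kb (horizontal axis), around 42001 (left) and 2878001 (right), with 1 line per library. At 42001 the values run from -0.76 to 0.06 and at 2878001 from -1.03 to 0.20.

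The other 8 of the 10 most variable bins, at 1931001, 96001, 1979001, 2082001, 2033001, 1901001, 14001 and 1713001, had ranges from 0.67 to 0.80 and deviations of at most 3.23 SD. They did not pass the limit. Over all 3993 bins the median range was 0.25, and counting alone gave 0.28. As counting alone gave more, this yardstick is too wide, and bins below the limit may still differ.

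No pair of libraries had identical counts. Among the 36 pairs the chi-square over its degrees of freedom ran from 0.83 for libraries 1 and 2 to 5.76 for libraries 3 and 6. Within the sampling noise were 4 pairs, namely 1 and 2 (0.83), 7 and 8 (0.89), 7 and 9 (0.90), and 8 and 9 (0.89). All 9 libraries were kept as separate libraries. The sampling noise set here is too wide a yardstick, because the scatter of reads around the trend was below binomial in 36 of 36 pairs.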

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

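Alternatives with corrected counts and with an origin window at the highest point were chosen after the data were seen, and the others before. Under the 9 alternatives run for the ratio, 34 to 36 of the 36 pairs of libraries kept their order. The terminus stayed in the same bin without any 1 library, which leaves the ratios as they were and says nothing of their stability. With no bin left out the ratios of libraries 1 to 9 were 2.74, 2.75, 2.49, 4.01, 4.09, 4.60, 3.43, 3.30 and 3.44, since empty bins then enter the origin window. With counts corrected for taken start positions they were 3.26, 3.29, 2.91, 4.94, 5.01, 5.53, 4.04, 3.99 and 4.10, since the correction raises full bins most. With windows of 200 kb either side, which take in bins farther from each end, they moved to 2.84, 2.85, 4.08, 4.09, 4.65, 3.54, 3.41 and 3.52 in libraries 1, 2 and 4 to 9. From the fitted lines they moved to 3.08, 2.99, 4.59, 4.88, 5.69, 4.18, 4.07 and 4.20 in libraries 1 and 3 to 9. The fitted lines give the ratio at the ends of the arms and not a mean over windows. How much of the move comes from this was not tested. Without the 200 kb next to the origin and the terminus, the right slope moved to -1.15, -1.28, -1.05, -1.04 and -1.05 per Mb in libraries 5 to 9, and the left slope to -0.81, -1.29, -1.07, -1.05 and -1.08 in libraries 3 and 6 to 9. The Theil-Sen slope of the right arm moved to -1.16, -1.27, -1.04, -1.02 and -1.04 in libraries 5 to 9, the quasi-Poisson fit to -1.15, -1.27 and -1.04 in libraries 5, 6 and 9, and a pseudocount of 5 to -1.21 in library 6. The cause of these moves of the slopes was not tested. The interval of left minus right slope included 0 in all 9 libraries under the Theil-Sen slope (with the width of the least squares interval), the terminus at the midpoint of the chromosome length and blocks of 100 bins. After each library's fitted line was divided out, 24 of the 36 pairs were within the sampling noise instead of 4, since the fitted gradient no longer separates them. Pairs still apart included libraries 3 and 5 (chi-square over its degrees of freedom 1.28) and 4 and 6 (1.15), so differences other than the fitted gradient remain. Of the 10 most variable bins, 9 were also named with 50 flanking bins on each side and 8 with a mean count of at least 100; with 50 flanking bins the ranges at 2878001 and 42001 were 1.25 and 0.85. Not run were the correction for base composition, the terminus at rtp and the local ratios at yabA, ccrZ and mobile elements, which need a genome or annotation of this build, the second table, whose values are the same, and the relation to total count. No paired analysis was possible because no library has a group. Depth limits single bins most near the terminus, and library 6, with a median of 194 reads per bin, has the widest counting error.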

Other observations

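Of the tests in this part, only the correction of library 3's counts for taken positions was set out before its result was seen. That result follows from counts already seen, and all other tests were chosen afterwards. No biological explanation was tested for any pattern, since no library has a group.

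The ratios have gaps between them, set here against intervals that hold only the unevenness of coverage within a library and not the spread between cultures, so they do not show that the cultures fall into sets. Sorted from low to high they are 2.69 (library 3), 2.96 (library 1), 2.97 (library 2), 3.57 (library 8), 3.71 (library 7), 3.72 (library 9), 4.34 (library 4), 4.42 (library 5) and 4.98 (library 6). Of the 8 steps between neighbours, 4 have intervals apart, those from library 3 to 1, from 2 to 8, from 9 to 4 and from 5 to 6. The step from library 3 to 1 depends on the measure: the fitted lines give 2.99 and 3.08, and the slope intervals of these libraries overlap on both arms. From library 9 to 4 the slope intervals are apart on the right arm only, and for the other 2 steps on both arms. The local ratios at the 2 variable places each have 1 wide gap. At 2878001 to 2879000, libraries 4, 5 and 6 have 0.07, 0.06 and 0.20, and the other 6 libraries lie from -1.03 to -0.57. At 42001 to 43000, libraries 1, 2 and 3 have 0.06, -0.02 and 0.05, and the other 6 libraries lie from -0.76 to -0.58. Libraries 7, 8 and 9 are low at both places, with -0.77, -0.71 and -1.03 at the first and -0.65, -0.65 and -0.76 at the second. These are values of single libraries and assign no strain. Across 7 clusters of empty runs, the median excess of the change in count over the arm's slope ran from -0.07 at 161001 to 176000, where single libraries had -0.16 to -0.02, to 0.07 at 10001 to 14000, where they had 0.04 to 0.10. The excess was also above 0 in 9 of 9 libraries at 31001 to 35000 and at 91001 to 101000 and below 0 in 9 of 9 at 599001 to 603000. For each cluster at least 7.93% of 769 places along the chromosome had a median excess as large.

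Reads were split between libraries more evenly than binomial sampling allows. Around the running trend the scatter was 0.889 of the binomial variance over all pairs and below 1 in 36 of 36 pairs, which share libraries and are not independent. From the emptiest to the fullest of 5 equal classes of bins the scatter was 0.925, 0.944, 0.900, 0.852 and 0.822, with a difference of -0.102 between the last and the first (95% interval -0.168 to -0.017). The removal of reads that share a start position may contribute, as it predicts such a fall, but 1 minus the count over 2000 strand positions gives 0.925, 0.902, 0.870, 0.829 and 0.775, which lies within the 95% interval of 4 of the 5 classes and below that of the second (0.912 to 0.975). Removing the trend does not produce it, since Poisson counts passed through the same steps gave 1.0 and no lower than 0.984 in 20 draws. The duplicate handling of these counts is not given in the sources used here, so this stays a hypothesis, and under it the ratios as deposited would understate the gradient.

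Library 3 was nearly level next to the origin, at 0.07 on the log2 scale where the other 8 libraries had 0.26 to 0.36. Removal of reads that share a start position, at the size that 2000 strand positions per bin imply, would not account for this. The value after correcting for it was 0.0803, and the other corrected values ran from 0.297 to 0.422. The correction is a fixed function of counts already seen, here medians of 437 near and 416 far, so it could move the value little. A larger loss of such reads was not tested. A wave of coverage not tied to the origin stays open: the profile of library 3 over the mean of the others mirrored itself about coordinate 1 with r = 0.888, the highest of its 161 axes, but this restates the dip on both arms, libraries 1 and 2 also had their highest r there (0.75 and 0.80), and library 4 reached 0.899 about another axis. Base composition was not measured, the culture of library 3 has no known density at harvest, and a difference in how its DNA was prepared stays open.

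The 10 runs of empty bins may be rRNA operons whose near-identical copies received no counted reads. The gene table of the reference strain lists 10 such operons, and the number of genes between neighbouring operons tracked the kb between neighbouring runs with a rank correlation of 0.997 over 10 spacings (1-sided permutation p = 1e-05, the smallest that 100000 draws can give). Neighbouring spacings on a circle are not independent, and the positions themselves were not matched to an annotation. The run at 2992001 to 2994000 was 2 kb long and the other 9 were 4 kb, a difference whose cause was not tested. Loss of these regions from all 9 libraries for another reason was not tested.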
